A study of Mus musculus with 8 samples.

How the data were processed

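Gene expression was measured in mouse liver with Affymetrix arrays, using 8 arrays from 4 genotypes and 2 arrays per genotype. Per the labels' protocols, total RNA was isolated with Tri-reagent and labelled with biotin by the manufacturer's standard procedure, and the mice were kept on standard chow in virus-free housing. Genotype and replicate number were taken from the sample titles. Nothing in the labels says that the arrays of a genotype came from separate animals, so the p-values measure the spread between these samples, which may be technical or a spread between pools.

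The deposited values are treated as log2 expression values, 1 per probe set and array, which the authors made with R 2.15.0 per the submitters' processing notes. The method of background correction and summarisation, any filter and the base of the logarithm are not given in the sources used here. Base 2 was taken from the range of the values, from 2.20 to 14.19 over all arrays. Array medians lay between 5.45 and 5.56 with near-equal quartiles, so the values were read as already normalised between arrays and were used as deposited, with no pseudocount and no filter on dim genes. Arrays give no count per gene, so it is the number of arrays that limits the precision.

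The table held 22690 probe sets. The 64 control probe sets were left out of the tests, which left 22626, and 20380 of these named 1 gene, 691 named several and 1555 named none. Gene names came from the array annotation, and 20351 gene IDs matched the RefSeq gene table of the assembly GRCm38.p6, which changed 0 symbols. That table was used for names and for the order of neighbouring genes, and no coordinates are given. Each gene was represented by its probe set with the highest mean over all arrays, which gave 12393 genes, of which 4956 had more than 1 probe set.

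A linear model with 1 mean per genotype was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for data handling. The model had 4 residual degrees of freedom, and empirical Bayes moderation, with trend and robust options off, added 7.16 prior degrees of freedom. The comparisons were SHP-/- minus wild-type, OB-/-/SHP-/- minus OB-/-, OB-/- minus wild-type, OB-/-/SHP-/- minus SHP-/-, the interaction (the difference between both SHP comparisons) and OB-/-/SHP-/- minus wild-type. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes within a comparison, and a gene was called at an adjusted p below 0.05. Errors are moderated standard errors (SE) of a difference between genotypes.

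There were 29 lists of genes, with 429 members of which 373 were measured, tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists within a comparison. The test was repeated with the correlation estimated for each list. In that form camera works with the 4 residual degrees of freedom, so p-values rise even where the correlation is low. For the lipid droplet list in OB-/- minus wild-type, the estimated correlation was 0.0196. Its unadjusted camera p was 5.7e-13 at the preset correlation and 0.00238 with the estimated one. A list lost in the repeat is therefore not shown to hold genes that vary together. Members past the threshold were counted over all genes and also adjusted over the list alone. The comparisons, the lists, the rule for naming genes and all but the last of the alternatives below were fixed before the data were examined. Under that rule, Nr0b2 and Lep were named, then the 10 largest rises and 10 largest falls past the threshold whose arrays did not overlap, whose higher mean reached the median of all values (5.50) and whose symbol was not a predicted or clone name. The rule went on to up to 4 members of each list by smallest adjusted p, and to up to 3 members by highest level for lists that did not pass, with values alone. For the interaction the condition on overlap was dropped. A further 7 lists were written after the largest changes had been seen. They were adjusted over these 7 alone within a comparison, and of the alternatives below only the estimated correlation was run on them.

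Agreement between comparisons that share no array was described across genes, which are not independent replicates. For comparisons that share the OB-/- arrays, chance was gauged with 100 simulations of a double knockout equal to OB-/- and by giving each comparison 1 of the OB-/- arrays.

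The alternatives were quantile normalisation, equal array medians, a filter on genes with a mean below the 40th percentile of probe sets (4.83), eBayes with trend, robust eBayes, the mean of a gene's probe sets, every probe set by itself, leaving out the x_at and s_at probe sets, a minimum change of 2-fold, a fit to the 4 arrays compared, the replicate number as a block, an estimated correlation for list tests, and each array left out in turn. With 1 array left out, its genotype keeps a single array, which is assumed to vary like the other genotypes. Other pseudocounts, foreseen for linear values, were not run because the values are logarithms. An alternative without both arrays in doubt was chosen after seeing the data. No genome was used here, so probe positions were not compared with the deleted part of Nr0b2.

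The steps were tested on simulated data with 200 changed genes among 12393 and 20 simulations. For SHP-/- minus wild-type, 24.3% of genes changed by 0.5 on the log2 scale were called and 98.5% of those changed by 1. For the interaction the shares were 4.1% at 0.5, 69.0% at 1 and 98.6% at 1.5. False calls made up 7.14% of calls in the first case and 7.20% in the second. Lists of 20 genes shifted by 0.5 had an unadjusted camera p below 0.05 in 20 of 20 simulations, and unshifted lists in 0 of 20, in either comparison. The simulated genes varied independently, whereas the correlation estimated for a fixed list reached 0.515. These simulations therefore do not test lists whose genes vary together.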

Results

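Liver RNA of mice from 4 genotypes was hybridised to 8 Affymetrix arrays, 2 for each of wild-type, SHP-/-, OB-/- and OB-/-/SHP-/- mice. SHP (small heterodimer partner, encoded by Nr0b2) is a nuclear receptor without a DNA-binding domain that represses other nuclear receptors, among them those that control bile acid synthesis. OB-/- mice lack leptin, the hormone of fat tissue that restrains feeding, and are obese with fatty livers. The design asks which liver genes depend on SHP in lean mice and in obese mice, and how far the obese profile depends on SHP. Array medians were 5.45 to 5.56 on the log2 scale. Across genes, arrays of 1 genotype correlated at r between 0.992 and 0.995, and arrays of different genotypes at r between 0.973 and 0.993. The first principal component held 57.1% of the variance and separated both leptin-null genotypes from both leptin-intact ones, and the second, with 15.5%, separated OB-/- from OB-/-/SHP-/-. The median SE of a difference between genotypes was 0.15 on the log2 scale.

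Nr0b2, measured by 1 probe set, stood at 8.74 and 8.71 in the wild-type arrays, 7.78 and 8.31 in SHP-/-, 8.01 and 8.01 in OB-/- and 7.11 and 6.66 in OB-/-/SHP-/-. Whether that probe set lies in the deleted part of the gene is not known here, so its signal may not test the knockout. SHP-/- minus wild-type was -0.68 ± 0.19 (SE), which did not pass the test (adjusted p = 0.286). Nr0b2 fell by 1.13 ± 0.19 in OB-/-/SHP-/- against OB-/- (adjusted p = 0.0108). With leptin loss and SHP absent, OB-/-/SHP-/- against SHP-/-, it fell by 1.16 ± 0.19 (adjusted p = 0.00372), a call kept with any single array left out. It fell by 0.72 ± 0.19 in OB-/- against wild-type (adjusted p = 0.0258) and fell by 1.84 ± 0.19 in OB-/-/SHP-/- against wild-type (adjusted p = 1.0e-04). The call against OB-/- was lost without either OB-/- array or without OB-/-/SHP-/- replicate 2 (adjusted p up to 0.106), and that of OB-/- against wild-type without any of its 4 arrays (up to 0.134). Lep lay between 3.16 and 3.53 on every array, near the low end of the table, and passed in no comparison.

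The arrays differed in ways that the genotype labels do not state. Xist, expressed from the inactive X chromosome of females, was 7.41 in OB-/- replicate 1 and between 4.31 and 4.70 on the other arrays, while the Y-linked Eif2s3y was between 6.57 and 7.50 on every array. The 3' probe set of Gapdh exceeded the 5' probe set by 0.90 in wild-type, 0.27 in SHP-/-, -0.04 in OB-/- and 0.07 in OB-/-/SHP-/-. For Actb the same offsets, which grow as RNA degrades, were 1.88, 1.30, 0.83 and 0.86. SHP-/- replicates were more than 2 log2 units apart at 17 genes, against 0 in wild-type, 1 in OB-/- and 4 in OB-/-/SHP-/-. Among them, the immediate-early gene Fos was 11.95 in SHP-/- replicate 1 and 6.98 in replicate 2, and the acute phase gene Saa2 was 8.98 and 12.23.

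The first comparison asked what SHP loss does in the liver of leptin-intact mice. Of 12393 genes, 40 changed, 28 up and 12 down. Asns, which makes asparagine, rose 7.15-fold (2.84 ± 0.38 on the log2 scale, adjusted p = 0.00997), and Csad, an enzyme of taurine synthesis, rose 3.93-fold (1.98 ± 0.18, adjusted p = 7.6e-04). Dct, an enzyme of melanin synthesis, rose by 2.68 ± 0.24, and the peroxisomal fatty acid transporter Abcd2 by 2.59 ± 0.43. Mpeg1, a pore-forming protein of macrophages, rose by 1.74 ± 0.18, with Smoc2 at 1.86, Tmem267 at 1.82, the cholinesterase Bche at 1.75, Cap1 at 1.73 and Mmd2 at 1.53. The largest falls were those of Dmbt1 (7.03-fold, -2.81 ± 0.19, adjusted p = 1.7e-04) and of Serpina12, which encodes the adipokine vaspin (4.06-fold, -2.02 ± 0.16, adjusted p = 3.9e-04). Dio1, the deiodinase that activates thyroid hormone, fell by 1.92 ± 0.30, and Pparg, the nuclear receptor of lipid storage, fell by 1.36 ± 0.18. Other falls were those of Cnmd (-1.71), Stmn1 (-1.33, with a further probe set at 0.01), Ighm (-1.25), Pde4b (-1.18) and the complement gene C9 (-0.86).

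Of the 29 lists, 9 passed camera in SHP-/- against wild-type and 0 of them held with an estimated correlation, where 1 list had an unadjusted p below 0.05. Here and below, that repeat has 4 degrees of freedom and little power, so its losses do not separate correlation between genes from few arrays. The macrophage marker list shifted up (adjusted p = 4.1e-10; adjusted p = 0.474 with an estimated correlation), with a median of 0.71 over 18 genes. Of these 0 passed over all genes by limma, 13 had an unadjusted p below 0.05, and 11 rose and 1 fell adjusted over the list alone. The list of the unfolded protein and integrated stress response shifted up (adjusted p = 9.5e-04; adjusted p = 0.474 with an estimated correlation), with a median of 0.18 over 18 genes, of which Asns alone rose, also adjusted over the list alone. Male-biased liver genes shifted down (adjusted p = 0.00861; adjusted p = 0.474 with an estimated correlation), with 1 of 9 past the threshold, Ugt2b38 at -1.67 ± 0.25, and 4 falling adjusted over the list alone. Bile acid synthesis shifted up by a median of 0.12 over 14 genes (adjusted p = 0.0238; adjusted p = 0.568 with an estimated correlation), with 0 members past the threshold over all genes. Of its members 3 had an unadjusted p below 0.05 and 1 rose adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, named here after its values were seen, differed by 0.82 ± 0.30 (adjusted p = 0.564). The lists of cholesterol synthesis, acute phase and methionine metabolism shifted up with medians of 0.11, 0.18 and 0.13 (adjusted p = 0.00111, 0.0134 and 0.0221; adjusted p = 0.543, 0.585 and 0.543 with an estimated correlation). They had 0 members past the threshold by limma and 3, 2 and 2 at an unadjusted p below 0.05, while adjusted over the list alone 2 rose, 1 rose and 1 fell, and 0 changed. Lipoprotein genes shifted up and markers of adjacent tissues down (medians 0.07 and -0.14, adjusted p = 0.0267 and 0.0252; adjusted p = 0.543 and 0.474 with an estimated correlation). Each had 1 member past the threshold over all genes and adjusted over the list alone, Pltp, a phospholipid transfer protein, at 0.89 ± 0.15 and the muscle actin Acta1 at -1.01 ± 0.17. The stearoyl-CoA desaturase Scd1 rose by 1.04 ± 0.19 within a fatty acid synthesis list that did not pass (adjusted p = 0.0804). SHP-/- and wild-type arrays also differed in RNA quality, with Gapdh offsets of 0.27 and 0.90.

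These counts leaned on single arrays. The number of genes was 5 without wild-type replicate 1, 14 (6 up and 8 down) without wild-type replicate 2, 67 without SHP-/- replicate 1, 95 without SHP-/- replicate 2 and 26 without either OB-/- array. With every probe set tested by itself, 83 rose and 17 fell. Of the genes named above, Dct, Csad, Dmbt1 and Serpina12 passed with any single array left out. Asns, Smoc2, Tmem267, Bche, Cap1 and Ighm were lost without either wild-type array (adjusted p up to 0.223), Abcd2 and Dio1 also without either OB-/- array (up to 0.311), and Mpeg1, Mmd2, Cnmd, Pparg, Stmn1 and Ugt2b38 without wild-type replicate 1 (up to 0.140). Pde4b, C9, Scd1, Pltp and Acta1 were each lost without at least 5 of the arrays, both wild-type and both OB-/- arrays among them. Without wild-type replicate 2 the adjusted p was 0.438 for the cholesterol list, 0.515 for bile acid synthesis, 0.123 for lipoproteins, 0.111 for methionine metabolism and 0.133 for adjacent tissues. Without SHP-/- replicate 1 the last 4 stood at 0.0604, 0.0604, 0.0925 and 0.0628, and without SHP-/- replicate 2 bile acid synthesis, lipoproteins and adjacent tissues at 0.0616, 0.0932 and 0.0562. The acute phase list was at 0.537 without wild-type replicate 1 and pointed down without SHP-/- replicate 2 (0.117).

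In leptin-null mice, OB-/-/SHP-/- minus OB-/- asked the same of SHP loss in obesity. Of 12393 genes, 265 changed, 156 up and 109 down. The 10 largest rises held 8 genes of interferon-inducible GTPases, which act in defence against intracellular microbes. Gbp6 rose 35.3-fold (5.14 ± 0.23, adjusted p = 3.4e-07), Gbp2 29.0-fold (4.86 ± 0.17, adjusted p = 7.2e-08) and Igtp by 4.14 ± 0.15, with Gbp2b at 4.93, Gbp7 at 4.07, Gbp3 at 3.79, Ifi47 at 3.43 and Irgm1 at 3.28. In a list of 14 such genes written after these rises were seen, 10 were measured and all 10 rose (median 3.93). The sulfotransferase Sult3a1 rose 24.3-fold (4.61 ± 0.27, adjusted p = 1.8e-06), and the protease Ctse by 3.30 ± 0.44 although its other probe set read -0.77. The largest fall was that of Cidea, a lipid droplet protein of fatty liver (23.0-fold, -4.52 ± 0.20, adjusted p = 3.4e-07). Colipase Clps (-3.31 ± 0.22), Reg3b (-3.15 ± 0.16), Zg16 (-2.94 ± 0.16) and the trypsinogen Prss2 (-2.79 ± 0.23) fell as well. Further probe sets of Reg3b and Zg16 read 0.02 and 0.16. Clps, Reg3b, Zg16 and Prss2 were brighter on both OB-/- arrays than on any other, and pancreas tissue in those samples was not excluded. Further falls were those of Adi1 of methionine salvage (-2.64), Olig1 (-2.61), Serpina12 (4.44-fold), the cytochrome Cyp2f2 (-2.07) and Dio1 (-1.97).

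Between OB-/-/SHP-/- and OB-/-, 7 lists passed camera, again 0 with an estimated correlation, where 1 list had an unadjusted p below 0.05. Lipid droplet genes shifted down (adjusted p = 0.0167; adjusted p = 0.652 with an estimated correlation), with 4 of 14 falling and, adjusted over the list alone, 6 falling and 1 rising: Cidea, Cidec at -1.65 ± 0.34, the fatty acid binding protein Fabp4 at -0.96 ± 0.16 and Fitm1 at -0.85 ± 0.15. Fatty acid and triglyceride synthesis shifted down (adjusted p = 0.0227; adjusted p = 0.652 with an estimated correlation), with 3 of 22 falling and, adjusted over the list alone, 6 falling and 1 rising: Mogat1 at -1.85 ± 0.25, the elongase Elovl6 at -1.14 ± 0.25 and ATP citrate lyase Acly at -1.01 ± 0.13, whose other probe set read 0.03. Stellate cell and fibrosis markers shifted down (adjusted p = 0.0227; adjusted p = 0.652 with an estimated correlation), with the collagens Col3a1 at -1.19 ± 0.21 and Col4a1 at -0.82 ± 0.13 past the threshold among 14, the same count of 2 adjusted over the list alone. Glycolysis shifted down and the acute phase list up (adjusted p = 0.0381 and 0.0227; adjusted p = 0.652 and 0.685 with an estimated correlation) with 0 members past the threshold by limma, 1 and 5 at an unadjusted p below 0.05 and, adjusted over the list alone, 0 and 2. Amino acid catabolism and methionine metabolism shifted up (both adjusted p = 0.0254; adjusted p = 0.652 with an estimated correlation) with 2 and 1 members rising over all genes and also adjusted over the list alone, Hal at 0.72 ± 0.16, Tat at 0.68 ± 0.15 and Cth at 0.74 ± 0.15. In lists that did not pass, the scavenger receptor Scarb1 rose by 1.09 ± 0.16, the sterol hydroxylase Cyp39a1 by 1.14 ± 0.17 and the insulin signalling adaptor Irs2 by 1.05 ± 0.19, and the cytochrome Cyp2b10 fell by 1.77 ± 0.18. Bile acid synthesis did not pass as a list (median 0.12, adjusted p = 0.130), and Cyp7a1 differed by -0.53 ± 0.30 (adjusted p = 0.559).

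The count was 97 without OB-/- replicate 1, 80 without OB-/- replicate 2, 162 without OB-/-/SHP-/- replicate 2 and 119 without both arrays in doubt, OB-/- replicate 1 and SHP-/- replicate 1. Olig1, Dio1, Cyp39a1 and Scarb1 were lost without OB-/- replicate 2 (adjusted p up to 0.0857) and Fabp4, Fitm1, Cidec, Col3a1, Col4a1 and Irs2 without either OB-/- array (up to 0.219). The call of Fabp4 was also lost without OB-/-/SHP-/- replicate 2 and those of Fitm1, Cidec, Col3a1 and Irs2 without OB-/-/SHP-/- replicate 1. Elovl6, Hal, Tat and Cth were lost without any of at least 5 arrays, OB-/- replicate 2 and both wild-type arrays among them (up to 0.432). Each of the 7 lists was lost without OB-/-/SHP-/- replicate 1, with adjusted p of 0.0819 for lipid droplets, 0.280 for fatty acid synthesis, 0.280 for the acute phase, 0.221 for stellate cells, 0.161 for amino acid catabolism, 0.126 for methionine metabolism and 0.138 for glycolysis. Without OB-/- replicate 2, 5 of them were lost, at 0.0957 for fatty acid synthesis, 0.0651 for the acute phase, 0.240 for amino acid catabolism, 0.0903 for methionine metabolism and 0.238 for glycolysis. Without OB-/- replicate 1 the stellate list was at 0.0567. The lists of methionine metabolism and glycolysis also stood at 0.0511 and 0.0560 without either SHP-/- array and both at 0.0568 without OB-/-/SHP-/- replicate 2.

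Set side by side, both SHP comparisons, which share no array, had log2 differences that correlated across genes at r = 0.186 (Spearman's rho 0.117). In both, 9 genes rose where independence gives 0.353, and 2 fell where it gives 0.106. Csad rose by 1.98 in leptin-intact and by 1.92 in leptin-null mice, Asns by 2.84 and 2.07, Mpeg1 by 1.74 and 1.70, and the imprinted noncoding RNA Meg3 by 1.46 and 1.84. Asns read 8.00 and 6.44 in OB-/-/SHP-/- replicates 1 and 2, so the size of its rise in leptin-null mice is uncertain. Serpina12 fell 4.06-fold and 4.44-fold, and Dio1 fell as well (-1.92 and -1.97). The other genes of the overlap were Cap1, Extl1, Mmd2, Rdh9 and Tmem71. Meg3, Extl1, Rdh9 and Tmem71 were named after their values were seen. Pltp alone moved in opposite directions, at 0.89 and -0.99, and its interaction of -1.87 ± 0.21 passed (adjusted p = 0.00128). Of the 40 genes called in leptin-intact mice, 31 (77.5%) had the same sign in leptin-null mice, with a slope through 0 of 0.438. Choosing these genes on the leptin-intact comparison lowers that slope by itself. No reverse slope was computed here, so it does not show a smaller effect in leptin-null mice. The interaction test, which asks for which genes the effect of SHP loss differed between leptin backgrounds, called 68 genes. The GTPases, Sult3a1, Ctse and Cidea were among them, with Gbp2 at 5.10 ± 0.25 and Cidea at -4.17 ± 0.29. The interaction count was 38 and 32 without wild-type replicates 1 and 2, 39 without either OB-/- array and 113 without SHP-/- replicate 2. Ctse was lost without either wild-type array (adjusted p up to 0.0585).

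**Figure D1:**
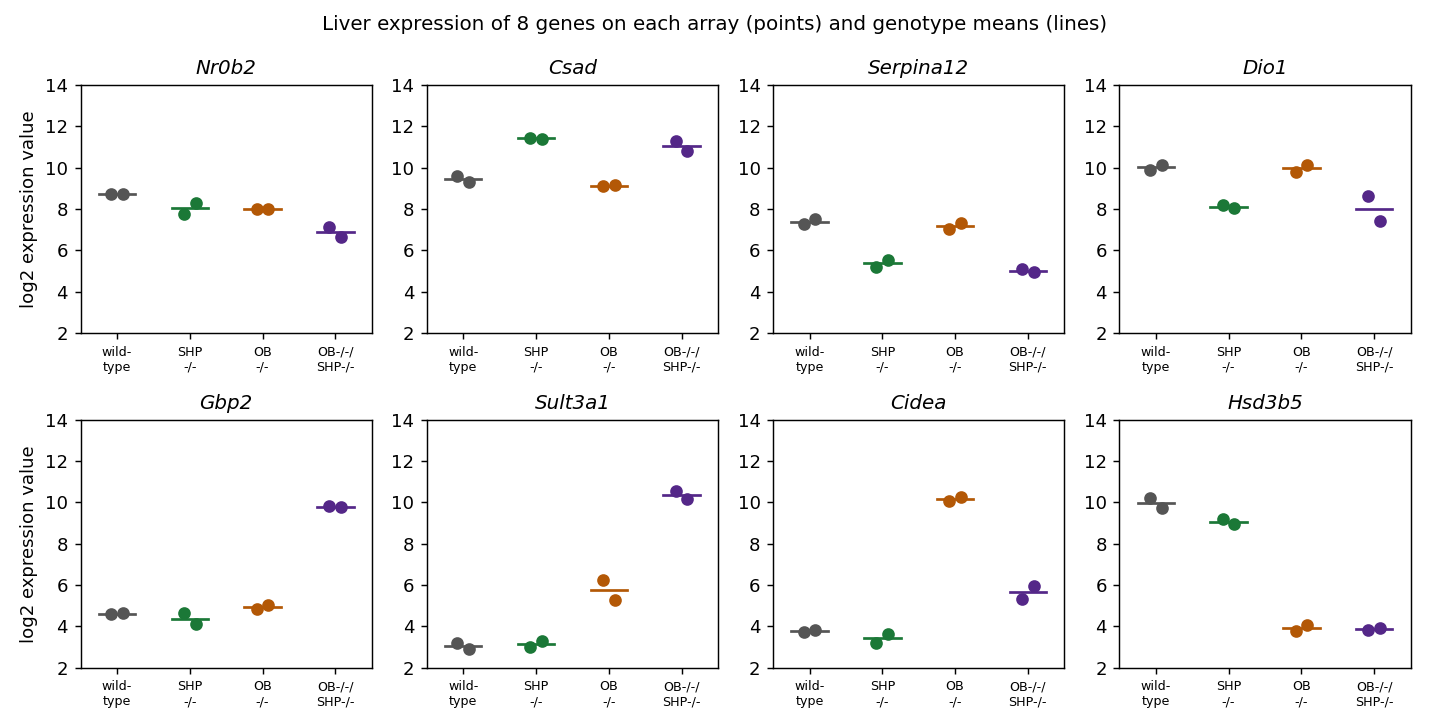
Log2 expression value on each array (points) and mean of each genotype (lines) for Nr0b2, Csad, Serpina12, Dio1, Gbp2, Sult3a1, Cidea and Hsd3b5, with 2 arrays per genotype. Csad was higher and Serpina12 lower in both genotypes without SHP, and Gbp2 stood at a mean of 9.80 in OB-/-/SHP-/- against 4.94 in OB-/- and less in the other genotypes.

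OB-/- minus wild-type measured leptin loss with SHP present. Of 12393 genes, 2100 changed, 940 up and 1160 down, or 847 up and 1359 down after shifting the arrays to equal medians and 531 up and 425 down without wild-type replicate 1. The sulfotransferase Sult2a2 rose 216-fold (7.75 ± 0.25, adjusted p = 1.1e-08) and Cidea 84.5-fold (6.40 ± 0.20, adjusted p = 1.1e-08). Other large rises were those of Lgals1 (4.87), Clps (4.49), the estrogen sulfotransferase Sult1e1 (4.30), Cidec (4.17), the fatty acid transporter Cd36 (3.91) and Pltp (3.90). The cytochromes Cyp2b13 and Cyp2b9 rose by 6.07 ± 1.23 and 4.95 ± 1.40. Both calls were lost without either wild-type array or without OB-/- replicate 2, and that of Cyp2b9 also without OB-/- replicate 1. The SE pools the spread of all genotypes, and the OB-/-/SHP-/- arrays, outside this comparison, read 4.55 and 10.31 for Cyp2b13 and 4.34 and 10.74 for Cyp2b9. Cyp2b13 read 4.47 and 4.56 in wild-type and 10.61 and 10.56 in OB-/-. Cyp2b9 read 5.84 and 7.08, and 11.44 and 11.37. The organic anion transporter Slco1a1 fell 87.8-fold (-6.46 ± 0.18, adjusted p = 8.1e-09), the steroid dehydrogenase Hsd3b5 66.5-fold (-6.05 ± 0.18) and the oxysterol hydroxylase Cyp7b1 41.5-fold (-5.37 ± 0.18). Igfbp2, a binding protein of insulin-like growth factors, fell by 5.64 ± 0.19. Further falls were those of Cox6b2 (-3.80), Asic5 (-3.59), Gdpd3 (-3.40), Scara5 (-3.38, with its other probe set at 0.04), Meg3 (-3.25) and the complement gene C8b (-3.24). Wild-type and OB-/- arrays differed in RNA quality, with 3' minus 5' offsets of 0.90 and -0.04 for Gapdh.

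Of the lists, 14 passed camera in OB-/- against wild-type and 0 held with an estimated correlation, where 6 had an unadjusted p below 0.05. Lipid droplet genes shifted up (adjusted p = 1.6e-11; adjusted p = 0.0690 with an estimated correlation), with 9 of 14 rising, as many adjusted over the list alone, among them Plin4 at 2.79 ± 0.17 and Fitm1 at 2.62 ± 0.15. Fatty acid and triglyceride synthesis shifted up (adjusted p = 3.4e-09; adjusted p = 0.119 with an estimated correlation), with 13 of 22 rising and 1 falling, and 16 and 2 adjusted over the list alone. Mogat1 rose by 3.76 ± 0.25, malic enzyme Me1 by 2.52 ± 0.15 and Scd1 by 1.94 ± 0.19. Male-biased liver genes shifted down (adjusted p = 4.2e-07; adjusted p = 0.119 with an estimated correlation), with 6 of 9 falling and 7 adjusted over the list alone. Female-biased genes shifted up (adjusted p = 2.1e-05; adjusted p = 0.119 with an estimated correlation), with 6 of 10 rising, as many adjusted over the list alone. Beside Hsd3b5 and C8b, the male-biased Cyp4a12a fell by 1.16 ± 0.16, and of the female-biased genes Hao2 rose by 2.78 ± 0.18 and Sult3a1 by 2.71 ± 0.27. The Y-linked Kdm5d fell by 1.12 ± 0.14 (a further probe set read 0.02) in a list of sex-linked genes that did not pass (adjusted p = 0.609). Kdm5d read 4.37 in OB-/- replicate 1, the array with the high Xist signal, 4.21 in OB-/- replicate 2 and 4.29 and 4.45 in OB-/-/SHP-/-, so its fall did not go with that array. Bile acid and sterol transport shifted down (adjusted p = 5.7e-04; adjusted p = 0.213 with an estimated correlation), with 6 of 11 falling and, adjusted over the list alone, 6 falling and 1 rising. In it the sterol exporter Abcg8 fell by 1.32 ± 0.19 and its partner Abcg5 fell by 1.00 ± 0.17. The stress response list shifted down (adjusted p = 0.00122; adjusted p = 0.180 with an estimated correlation), with 7 of 18 falling and 8 adjusted over the list alone, among them Asns (-2.75 ± 0.38) and Creld2 (-1.08 ± 0.13).

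Cell cycle genes shifted up in OB-/- (adjusted p = 7.8e-07; adjusted p = 0.158 with an estimated correlation), with 10 of 19 rising and 11 adjusted over the list alone, Rrm2 by 2.07 ± 0.26 and Cdk1 by 1.86 ± 0.16. Of 5 lists of markers of other liver cells, 3 shifted up, while biliary epithelial and lymphocyte markers did not pass (medians -0.06 and -0.03, adjusted p = 0.953 and 0.956). Macrophage markers (adjusted p = 4.0e-06; adjusted p = 0.316 with an estimated correlation) had 10 of 18 rising and, adjusted over the list alone, 10 rising and 2 falling, C1qb by 2.13 ± 0.30 and Vsig4 by 1.88 ± 0.20. Endothelial markers (adjusted p = 8.6e-04; adjusted p = 0.408 with an estimated correlation) had 5 of 11 rising, as many adjusted over the list alone, with Lyve1 at 3.31 ± 0.28. Stellate cell markers (adjusted p = 0.00448; adjusted p = 0.408 with an estimated correlation) had 5 of 14 rising and 6 adjusted over the list alone, with Col4a1 at 1.52 ± 0.13. Fatty acid oxidation shifted up (adjusted p = 0.00177; adjusted p = 0.316 with an estimated correlation), with 7 of 18 rising and 9 adjusted over the list alone, among them Aldh3a2 at 1.01 ± 0.14. The oxidative stress list shifted up (adjusted p = 0.00444; adjusted p = 0.316 with an estimated correlation), with 5 of 12 rising and 2 falling, as many adjusted over the list alone, and Gstm3 at 3.27 ± 0.17. Glycolysis shifted up (adjusted p = 0.0171; adjusted p = 0.316 with an estimated correlation), with 4 of 9 rising and 1 falling, and 5 and 1 adjusted over the list alone. Pyruvate kinase Pklr rose by 2.00 ± 0.21. The acute phase list shifted down (adjusted p = 0.0286; adjusted p = 0.634 with an estimated correlation), with 1 of 18 rising and 4 falling, and 1 and 5 adjusted over the list alone, but its adjusted p was 0.225 without wild-type replicate 2 and 0.0811 without OB-/- replicate 2. Bile acid synthesis did not pass (median 0.14, mean -0.21, adjusted p = 0.905), and within it Cyp7b1 fell while Akr1d1 rose by 1.79 ± 0.17. The genes for the nuclear receptors Hnf4a and Rxra read -0.76 and -0.73 on their brightest probe sets and up to 1.24 and 0.54 on others. The count was 956 and 1165 without wild-type replicates 1 and 2, 1061 and 993 without OB-/- replicates 1 and 2, and 1121 without both arrays in doubt.

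OB-/-/SHP-/- minus SHP-/- measured leptin loss with SHP absent. Of 12393 genes, 1311 changed, 614 up and 697 down. The split was 534 up and 809 down after shifting the arrays to equal medians, 673 up and 634 down without OB-/-/SHP-/- replicate 1 and 368 up and 349 down without SHP-/- replicate 2. Sult2a2 rose by 7.91 ± 0.25, Sult3a1 by 7.22 ± 0.27, Sult1e1 by 5.62 ± 0.47, Cd36 by 4.35 ± 0.14 and Lgals1 by 3.55 ± 0.28, along with the GTPases Gbp2 (5.42), Gbp6 (5.27), Gbp2b (4.70), Igtp (3.61) and Gbp3 (3.54). The largest falls were those of Slco1a1 (-6.25 ± 0.18), Hsd3b5 (-5.20 ± 0.18), Igfbp2 (-5.00 ± 0.19) and Cyp7b1 (-4.69 ± 0.18). The oxidase Nox4 (-3.88), Susd4 (-3.56), Asns (-3.51) and the complement gene C6 (-3.31) followed. Fos and Egr1 read -4.05 ± 1.09 and -3.35 ± 0.53, but both were high in SHP-/- replicate 1, and Fos was lost without any array other than those of SHP-/- (adjusted p up to 0.164). Cyp7a1 fell by 1.07 ± 0.30 (adjusted p = 0.0455), a call lost without either SHP-/- array, either OB-/- array or OB-/-/SHP-/- replicate 2 (up to 0.309).

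In the same comparison 9 lists passed camera and 0 held with an estimated correlation, where 6 had an unadjusted p below 0.05. Lipid droplet genes shifted up with 9 of 14 rising and 11 adjusted over the list alone (adjusted p = 3.2e-12; adjusted p = 0.0616 with an estimated correlation), Pparg by 2.17 ± 0.18. Fatty acid synthesis shifted up with 7 of 22 rising and, adjusted over the list alone, 10 rising and 1 falling (adjusted p = 2.7e-05; adjusted p = 0.218 with an estimated correlation). Cell cycle genes shifted up with 8 of 19 rising and 9 adjusted over the list alone (adjusted p = 2.0e-06; adjusted p = 0.168 with an estimated correlation). The stress response list shifted down with 9 of 18 falling and 1 rising, and 10 and 1 adjusted over the list alone (adjusted p = 2.0e-06; adjusted p = 0.150 with an estimated correlation). In it the chaperone Hspa5 fell by 0.94 ± 0.14. Male-biased genes shifted down with 3 of 9 falling and 4 adjusted over the list alone (adjusted p = 1.3e-05; adjusted p = 0.150 with an estimated correlation). Female-biased genes shifted up with 4 of 10 rising and, adjusted over the list alone, 5 rising and 1 falling (adjusted p = 2.0e-04; adjusted p = 0.150 with an estimated correlation). Bile acid transport shifted down with 3 of 11 falling and, adjusted over the list alone, 4 falling and 1 rising (adjusted p = 0.00851; adjusted p = 0.387 with an estimated correlation). The bile salt export pump Abcb11 fell by 0.96 ± 0.16. Macrophage and endothelial markers shifted up, each with 3 rising, of 18 and 11, and with 7 and 4 adjusted over the list alone (adjusted p = 0.00305 and 0.0371; adjusted p = 0.626 with an estimated correlation for both). Without SHP-/- replicate 2 they stood at 0.294 and 0.448, and without OB-/-/SHP-/- replicate 1 the endothelial list at 0.163. The count of genes was 717 without SHP-/- replicate 2, 600 without OB-/-/SHP-/- replicate 2, 615 in a fit to the 4 arrays compared and 632 without both arrays in doubt.

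Leptin loss moved many of the same genes with and without SHP. The log2 differences of both comparisons, which share no array, correlated across genes at r = 0.721 (rho 0.651), with 360 genes rising in both where independence gives 46.6, 481 falling in both where it gives 65.2. Another 12 moved in opposite directions. Of the 2100 genes called with SHP present, 1990 (94.8%) had the same sign without SHP, and the slope through 0 of the second difference on the first was 0.650. Choosing genes on 1 comparison lowers such a slope by itself, and the reverse slope over the 1311 genes called without SHP was 0.822. With genes chosen on 1 OB-/- array and measured on the other, the slope was 0.678 over 993 genes and 0.663 over 1061. Both steps still used the same wild-type arrays, so their error, and any error common to both OB-/- arrays, can still lower the slope.

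**Figure D2:**
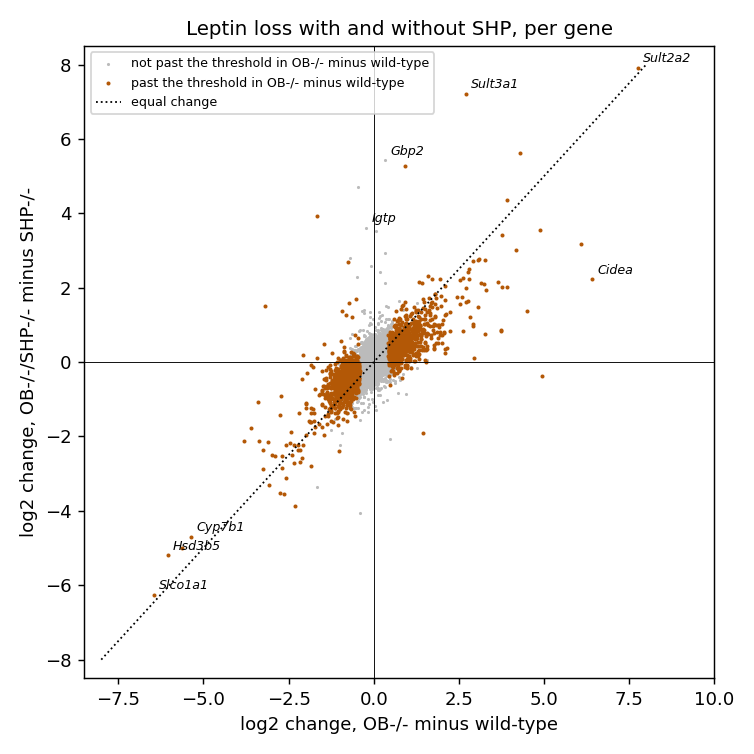
Log2 difference of each gene after leptin loss with SHP present (OB-/- minus wild-type, x axis) and with SHP absent (OB-/-/SHP-/- minus SHP-/-, y axis), where orange points are genes past the threshold in the first comparison and the dotted line marks equal differences. The genes called in the first comparison follow a slope of 0.650 through 0, with Cidea far below the dotted line and Gbp2 far above it.

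Of the 2100 genes changed by leptin loss with SHP present, 1545 (73.6%) had the opposite sign in OB-/-/SHP-/- minus OB-/-. Both comparisons use the OB-/- arrays, and in 100 simulations of a double knockout equal to OB-/- the share was 61.0% at the median and 58.8% to 63.3% in range. The simulated genes varied independently, so the range is too narrow for genes that vary together. The observed means were also taken as true, which can lower the simulated share. The simulations therefore do not exclude chance for the observed share. With 1 OB-/- array for each comparison, so that none was shared, the share was 65.7% over 993 genes and 68.1% over 1061. Among 161 genes past the threshold in both comparisons, 145 moved in opposite directions, which sharing the OB-/- arrays favours by itself. With none shared, a test chosen after this count was seen, it was 43 of 46 and 38 of 41. Such a split removes shared error only if the OB-/- arrays are separate samples, which the labels do not state. Genes that moved in opposite directions included Cidea (6.40 and -4.52), Clps (4.49 and -3.31), Cidec (4.17 and -1.65) and Mogat1 (3.76 and -1.85). Clps was bright on both OB-/- arrays, where 5 of 20 listed exocrine pancreas genes also rose and 1 fell. Pancreas tissue in those samples was not excluded.

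OB-/-/SHP-/- minus wild-type showed how far the double mutant lay from wild-type. Of 12393 genes, 1965 changed, 942 up and 1023 down, or 788 up and 1310 down after shifting the arrays to equal medians. Without wild-type replicate 1 the split was 484 up and 336 down, and with every probe set tested by itself 1794 up and 1556 down. Sult2a2 (7.67 ± 0.25), Sult3a1 (7.31 ± 0.27), Sult1e1 (7.05 ± 0.47) and Cd36 (3.79 ± 0.14) rose, as did Gbp6 (6.06), Gbp2 (5.18), Gbp2b (4.48), Igtp (3.91), Gbp3 (3.86) and Gbp7 (3.38). Slco1a1 (-6.83 ± 0.18), Hsd3b5 (-6.11 ± 0.18), Igfbp2 (-5.29 ± 0.19) and Cyp7b1 (-5.10 ± 0.18) fell most, followed by Nox4 (-3.37), C6 (-3.21), Susd4 (-3.10), Cyp2c23 (-2.94), Mcm10 (-2.82) and Abca8a (-2.77). Cidea was 1.88 ± 0.20 above wild-type, against 6.40 in OB-/-. Gapdh offsets of 0.90 and 0.07 mark the difference in RNA quality between these genotypes.

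Against wild-type, 13 lists passed camera in the double mutant and 0 held with an estimated correlation, where 5 had an unadjusted p below 0.05. Lipid droplet genes shifted up with 9 of 14 rising and 10 adjusted over the list alone (adjusted p = 4.7e-10; adjusted p = 0.0888 with an estimated correlation). Macrophage markers did so with 13 of 18 rising and, adjusted over the list alone, 14 rising and 1 falling (adjusted p = 2.0e-07; adjusted p = 0.361 with an estimated correlation), and fatty acid synthesis with 10 of 22 rising and 1 falling, and 12 and 1 adjusted over the list alone (adjusted p = 1.7e-06; adjusted p = 0.184 with an estimated correlation). Cell cycle genes shifted up with 10 of 19 rising, as many adjusted over the list alone (adjusted p = 2.5e-06; adjusted p = 0.184 with an estimated correlation), the cell cycle inhibitor Cdkn1a by 2.32 ± 0.29. Male-biased genes shifted down with 5 of 9 falling and 6 adjusted over the list alone (adjusted p = 2.0e-07; adjusted p = 0.117 with an estimated correlation). Female-biased genes shifted up with 4 of 10 rising, as many adjusted over the list alone (adjusted p = 6.0e-06; adjusted p = 0.117 with an estimated correlation). The stress response list shifted down with 7 of 18 falling and 1 rising, and 8 and 1 adjusted over the list alone (adjusted p = 0.00743; adjusted p = 0.261 with an estimated correlation). The other 6 had adjusted p between 0.0273 and 0.0475 (adjusted p from 0.458 to 0.610 with an estimated correlation) and were each lost when 1 array was left out. Bile acid transport, down, was at 0.0591 without wild-type replicate 1, and fatty acid oxidation, up, at 0.0557 without that array and 0.0984 without OB-/-/SHP-/- replicate 1. Lipoproteins, endothelial markers, oxidative stress and cholesterol synthesis, up, were at 0.0624, 0.368, 0.123 and 0.430 without wild-type replicate 2 and at 0.144, 0.140, 0.149 and 0.0915 without OB-/-/SHP-/- replicate 1. The cholesterol list was also lost without either SHP-/- array (0.0572) and without OB-/-/SHP-/- replicate 2 (0.0576). In these 6, the members past the threshold were 1 up and 4 down of 11 for bile acid transport, 3 up of 18 for fatty acid oxidation, 5 up of 16 for lipoproteins, 4 up of 11 for endothelial markers, 5 up and 2 down of 12 for oxidative stress and 5 up and 2 down of 19 for cholesterol synthesis. Adjusted over the list alone these were 1 and 4, 5, 5, 4, 6 and 2, and 6 and 2. The count of genes was 820 and 949 without wild-type replicates 1 and 2, and 1027 without OB-/-/SHP-/- replicate 2.

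**Figure D3:**
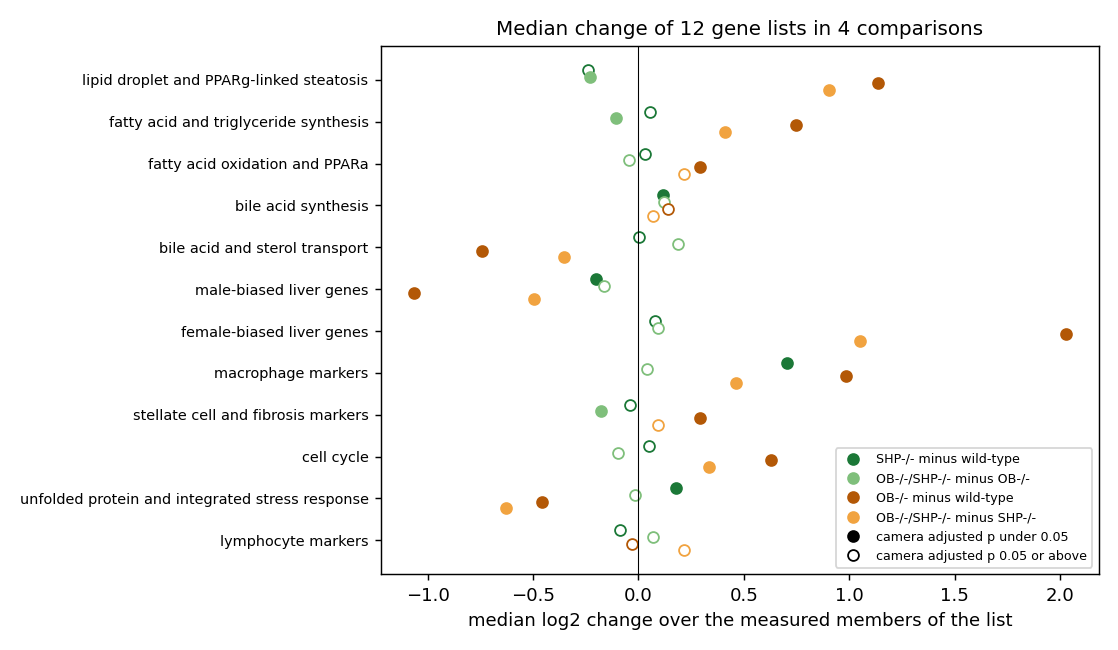
Median log2 difference of the measured members of 12 gene lists in 4 comparisons, where filled points are lists with an adjusted p below 0.05 by camera at the preset correlation. Lipid droplet genes had a median of 1.14 after leptin loss with SHP present and 0.90 with SHP absent. None of the filled points held with an estimated correlation, a test with 4 degrees of freedom.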

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

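The tests on the interferon-inducible GTPases and on the genes near Nr0b2 were chosen after those results were seen, and the test of RNA quality was written down before its result was seen.

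The interferon-inducible GTPases were higher in OB-/-/SHP-/- livers than in the other genotypes, and their effect of SHP loss differed between leptin backgrounds. The median interaction was 3.48 over 10 genes, each past the threshold over all genes. Their list was written after the largest changes, most of these genes among them, had been seen. In 10 of 10 measured genes the lower OB-/-/SHP-/- array lay above each of the other 6 arrays. For the 8 among the largest rises against OB-/-, the naming rule already required no overlap with OB-/-, so the count tests little for them. Irgm2 was named for its large interaction (2.77), so its gap of 2.02 to the highest other array is not independent support either. Iigp1 was not named by the rule. Its lower OB-/-/SHP-/- array exceeded the highest other array by 1.28, which argues against a single aberrant array for that gene alone. RNA of T and NK cells is argued against as the whole source, since the median of 16 of their markers differed by 0.071 (SD 0.20) between OB-/-/SHP-/- and OB-/-, where at least 1 was set as needed. The type I interferon list rose in part, with 10 of 21 measured members past the threshold (adjusted p = 0.00170 with an estimated correlation), so an infection or housing exposure of these mice may be the cause, although the labels state virus-free housing. For the part confined to these 2 arrays, such an exposure and an effect of losing both leptin and SHP cannot be told apart. The type I interferon list also shifted up on other arrays, in SHP-/- against wild-type, by a median of 0.31. There 0 of 21 passed over all genes and 7 adjusted over the list alone (camera adjusted p = 0.0180 over the 7 added lists, with an estimated correlation). Macrophage markers had a median of 0.71 in that comparison, and the Gapdh offset was 0.27 against 0.90 in wild-type.

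Some genes near Nr0b2 changed after SHP loss. Among the 30 tested genes on each side of Nr0b2, in the gene order of GRCm38.p6, 2 of 60 (Extl1 and Stmn1) were called in SHP-/- against wild-type and 38 of 12316 elsewhere (Fisher's exact test, two-sided, p = 0.0160), and 4 of 60 (Extl1, Paqr7, Rcc1 and Rsrp1) in OB-/-/SHP-/- against OB-/- (p = 0.0389). A candidate explanation is DNA of the embryonic stem cells used for targeting that stayed around the gene, but over 3 window sizes and 2 comparisons the adjusted p was 0.0961 and 0.115, and with 10 genes on each side 0 of 20 were called in either (Fisher's exact p = 1). Too few genes were called for the test to decide, so such DNA and an effect of SHP loss cannot be told apart for these genes. In OB-/- against wild-type, a control in which Nr0b2 was not targeted, 9 of the 60 were called (Fisher's exact p = 0.863).

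The 3' minus 5' offsets of the control genes differed between wild-type and OB-/- arrays, so RNA quality could enter the 2100 calls of leptin loss. SHP-/- arrays differed from wild-type in the same offsets by 0.668 (Gapdh) and 0.549 (Actb) of the difference between OB-/- and wild-type. Over the 2100 genes, the slope of SHP-/- minus wild-type on OB-/- minus wild-type was 0.12, and 0.105 to 0.147 with 1 array left out (SD 0.0159), although sharing the wild-type arrays pushes that slope up. RNA quality as the whole cause is argued against, since a slope below 0.3 by more than that SD had been set as excluding it. A part of the calls may still come from it, and leptin loss stays open as the explanation of the rest.

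The test of a difference in SHP effect between leptin-intact and leptin-null mice singled out 68 genes. The interaction was 5.15 for Gbp2b, 5.10 for Gbp2, 4.69 for Ctse, 4.51 for Sult3a1, 4.35 for Gbp6, 3.84 for Igtp, 3.48 for Gbp7, 3.47 for Gbp3, 3.44 for Ifi47 and 2.77 for Irgm2. Further positive values were 1.66 for Irs2, 1.32 for Ighm and 1.27 for Cyp2c37. The interaction was -4.17 for Cidea, -3.36 for Adi1, -3.13 for Clps, -2.90 for Prss2, -2.86 for Zg16, -2.84 for Reg3b, -1.93 for Mme, -1.91 for Wfdc2, -1.87 for Pltp, -1.78 for Cbr3, -1.60 for Cyp2b10 and -1.51 for Col4a1. Probe sets disagreed for Ctse (-2.97 on the other), Zg16 (0.22) and Reg3b (0.22). Clps, Prss2, Zg16 and Reg3b were brightest on the OB-/- arrays, where pancreas tissue in the samples was not excluded. Irs2, Ighm, Cyp2c37, Ctse, Mme and Cyp2b10 were lost without either wild-type array, and all of these but Ctse and Mme also without either OB-/- array (adjusted p up to 0.219).

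By list, the interaction was negative for fatty acid and triglyceride synthesis (adjusted p = 0.00108), macrophage markers (0.00260), stellate cell markers (0.00580), glycolysis (0.00866) and oxidative stress (0.0142), and positive for male-biased genes (0.00692) and the circadian clock (0.00866), with medians of -0.31, -0.47, -0.25, -0.30, -0.15, 0.66 and 0.36. With an estimated correlation, 0 of the 7 held in camera (adjusted p from 0.545 to 0.679), and 0 lists had an unadjusted p below 0.05. Over all genes Col4a1 and Cbr3 were the members past the threshold. Adjusted over the list alone and in the order above, 7 of 22, 4 of 18, 3 of 14, 2 of 9 and 1 of 12 fell, 3 of 9 male-biased genes rose and 0 of 16 clock genes passed. Where 0 members passed over all genes by limma, 8 members of fatty acid synthesis, 6 of macrophage markers, 2 of glycolysis, 5 of male-biased genes and 2 of the clock list had an unadjusted p below 0.05. Fatty acid synthesis passed with any array left out. Without SHP-/- replicate 1, glycolysis was at 0.0590, macrophage and stellate markers at 0.0781 and oxidative stress at 0.0548. Without OB-/-/SHP-/- replicate 1, male-biased genes were at 0.180, macrophage markers at 0.0674 and stellate markers at 0.0920. The clock list was at 0.138 without SHP-/- replicate 2 and 0.0544 without OB-/- replicate 2, glycolysis at 0.0629 without OB-/- replicate 2, and oxidative stress at 0.116 without wild-type replicate 2 and 0.0651 without OB-/-/SHP-/- replicate 2.

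Probe sets that name no single gene were outside the comparisons, and some of them passed when every probe set was tested by itself. Their number was 13 in SHP-/- minus wild-type, 32 in OB-/-/SHP-/- minus OB-/-, 285 in OB-/- minus wild-type, 170 in OB-/-/SHP-/- minus SHP-/-, 16 in the interaction and 284 in OB-/-/SHP-/- minus wild-type.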

How the results depend on the processing

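The alternative without both arrays in doubt was chosen after the data were seen. Quantile normalisation, equal array medians, the filter on dim genes, robust eBayes, the mean of a gene's probe sets and dropping x_at and s_at probe sets kept each of the 6 gene counts within 1.5 times its value. The count for SHP-/- minus wild-type was 68 with an eBayes trend and 23 in a fit to the 4 arrays compared, and that for OB-/-/SHP-/- minus SHP-/- was 615 in such a fit; the cause was not tested. With every probe set tested by itself, which raises the number tested, the counts were 100 for SHP-/- minus wild-type, 3592 for OB-/- minus wild-type, 120 for the interaction and 3350 for OB-/-/SHP-/- minus wild-type. A minimum of 2-fold, which removes calls by construction, left 116 in OB-/-/SHP-/- minus OB-/-, 510 in OB-/- minus wild-type, 318 in OB-/-/SHP-/- minus SHP-/- and 434 in OB-/-/SHP-/- minus wild-type. Without both arrays in doubt, and so with fewer samples, the counts were 119 in OB-/-/SHP-/- minus OB-/-, 1121 in OB-/- minus wild-type, 632 in OB-/-/SHP-/- minus SHP-/- and 39 for the interaction.

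With the replicate number as a block the counts were 51, 275, 2147, 1359, 77 and 1960, in the order SHP-/- minus wild-type, OB-/-/SHP-/- minus OB-/-, OB-/- minus wild-type, OB-/-/SHP-/- minus SHP-/-, interaction and OB-/-/SHP-/- minus wild-type. Replicate differences correlated across genes at 0.103 to 0.196 in the 3 genotype pairs without SHP-/- and at -0.107 to -0.008 in the 3 pairs with it. Not every array thus deviated with its own number. A common factor that ran against the numbers of the SHP-/- arrays would give the same signs, and the block by number cannot test it. A shared batch is therefore not excluded. With 1 array left out, the counts in that order ranged from 5 to 95, 80 to 298, 956 to 2234, 600 to 1307, 32 to 113 and 820 to 1998. The correlation of both SHP comparisons ranged from 0.148 to 0.192, and was 0.217 without dim genes, the cause of which was not tested. The slope of the leptin effect ranged from 0.619 to 0.687, the share of opposite movement from 68.0% to 80.5%, and the number of list tests passed, of 174, from 46 to 63 against 59 with all arrays. With an estimated correlation, in a test with 4 degrees of freedom, that number was 0.

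Of 407 calls of named genes, 254 passed under each alternative run on them, and 3 turned with the mean of a gene's probe sets, whose probe sets disagree: Hnf4a at 0.14 in OB-/- minus wild-type and 0.41 in OB-/-/SHP-/- minus wild-type, and Rxra at 0.092 in the latter. The acute phase list in SHP-/- minus wild-type ranged from an adjusted p of 3.7e-11 to 0.537 with 1 array left out and pointed down without SHP-/- replicate 2 (0.117), the replicate with the higher acute phase genes. Dim genes are limited by signal over background, and 8263 of 12393 genes lay at or above 4.83 on the log2 scale.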

Other observations

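The added lists named here were written after the largest changes had been seen, and their tests were chosen then. Their p-values were adjusted over 7 lists, against 29 for the macrophage list, and none was tested with an array left out. In SHP-/- against wild-type the unadjusted camera p with an estimated correlation was 0.00257 for type I interferon, 0.0182 for class I and 0.0132 for Dlk1-Dio3. Whether these lists hold may thus depend on the number of lists adjusted over.

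Beyond the GTPases, genes of class I antigen processing and presentation rose in OB-/-/SHP-/- against OB-/-, with 6 of 10 measured members past the threshold, as many adjusted over the list alone, and a median of 0.89 (adjusted p = 0.00323 with an estimated correlation). Interferon regulators and chemokines shifted up with 3 of 14 past the threshold, 6 adjusted over the list alone and a median of 0.37 (adjusted p = 0.0368 with an estimated correlation). In SHP-/- against wild-type, limma called 0 of 21 type I interferon genes, but 18 of 21 differences were positive, 7 rose adjusted over the list alone, and the list shifted up by a median of 0.31 (adjusted p = 0.0180 with an estimated correlation). In the same comparison macrophage markers had a median of 0.71, a shift that did not hold (adjusted p = 0.474 with an estimated correlation), and the Gapdh offset was 0.27 against 0.90 in wild-type. The class I list had 9 of 10 positive differences there and a median of 0.20 (adjusted p = 0.0424 with an estimated correlation), with 0 members past the threshold by limma over all genes or over the list alone. The GTPase list had a median of 0.33 there and did not hold (adjusted p = 0.0531 with an estimated correlation).

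Of the imprinted Dlk1-Dio3 region, listed after Meg3 and Rian had been seen, 3 transcripts were measured. Meg3 and Rian rose by 1.46 and 1.47 in SHP-/- against wild-type (adjusted p = 0.0424 for the list with an estimated correlation) and fell in OB-/-/SHP-/- against SHP-/- (-2.87 and -2.71, adjusted p = 0.0395 for the list with an estimated correlation). These 2 genes prompted the list, so its p-values add nothing to their own calls. In OB-/- against wild-type these 2 of 3 passed, at -3.25 and -2.34, but the list did not hold (adjusted p = 0.310 with an estimated correlation). In OB-/-/SHP-/- against OB-/- only Meg3 passed, at 1.84, and the list did not hold (adjusted p = 0.0611 with an estimated correlation).

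Clps and Prss2 were brighter in OB-/- livers than in the other genotypes. Zg16 (8.96 and 8.95) and Reg3b (6.33 and 6.75) were as well, against at most 6.25 and 3.60 on the other arrays. Clps was 7.95 and 7.15 in the OB-/- arrays, 4.28 and 4.20 in OB-/-/SHP-/- and at most 3.23 in the leptin-intact arrays, and Prss2 was 7.87 and 7.00, 4.53 and 4.75, and at most 3.85. A list of 20 measured genes of the exocrine pancreas was tested without Clps and Prss2. In OB-/- minus wild-type, 5 rose, 1 fell, 18 of 20 differences were positive and the median was 0.38. Adjusted over the list alone, 6 rose and 1 fell (camera adjusted p = 1.5e-04, or 0.393 with an estimated correlation). In OB-/-/SHP-/- minus OB-/-, 2 fell, 15 of 20 differences were negative and the median was -0.24. Adjusted over the list alone, 6 fell (camera adjusted p = 7.6e-06, or 0.112 with an estimated correlation). Pancreas tissue in the OB-/- samples and expression in the liver cannot be told apart here.

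Arrays of 1 genotype stood apart at a few genes. SHP-/- replicate 1 and replicate 2 read 10.74 and 6.95 for Jun, 11.38 and 9.12 for Egr1, 6.52 and 4.26 for Atf3, 9.87 and 12.60 for Saa1 and 8.79 and 11.43 for Lcn2. OB-/-/SHP-/- replicate 1 and replicate 2 read 4.34 and 10.74 for Cyp2b9, 4.55 and 10.31 for Cyp2b13 and 8.22 and 10.57 for Cyp2c39, while both OB-/- arrays read 11.44 and 11.37 for Cyp2b9.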
